A study of Mus musculus with 25 samples.

How the data were processed

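Total RNA was measured in 25 libraries from mouse heart. The tissue had been frozen and sectioned, and the sinoatrial node (SAN) or right atrium (RA) was outlined by eye and collected by laser capture. The sections were stained for Hcn4 after capture, as the check of the dissection. The RNA was amplified with a single primer isothermal method before library construction, and the libraries carry no strand information. Reads were assigned to whole genes, so genes with close paralogs (hemoglobins, the Ifit, Oas and Mx families) share reads in ways that these values cannot separate.

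The deposited values are a processed signal for 20870 genes in 25 libraries. Per the submitters' processing notes, reads were aligned with TopHat2 and scaled with edgeR, and the build given is mm8. The annotation used here for names is a later build, in which 18205 of the 20870 symbols (87.2%) were found, so no coordinates are given. Within each library at least 99.98% of the values were whole multiples of one step, within 0.1 of a read. The values were therefore taken as whole reads divided by a factor per library, and the reads were recovered by dividing by that step. Other units were considered in the design, and the alternatives for counts were run on the recovered reads.

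Recovered reads numbered 5101711 to 17997497 per library in the 18 libraries of the tissue and stage set and 45298052 to 88020475 in the 7 libraries of the Isl1 set. A single read was worth between 0.00823 and 0.215 of the unit used here, and at most 0.0177 in the Isl1 set. A count of 0 allows up to 3 reads. Intervals and floors cover counting error only, since amplified reads are not independent molecules. Between replicates the spread was larger than counting error in each group, by a factor of at least 8.82 (chi-squared over its degrees of freedom). Between 15657 and 19206 genes were detected per library. No column was left unused.

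The deposited values were divided by one constant, 24.3, so that the mean library total matches the usual CPM scale, and the result is called CPM. This constant was chosen after the scale of the file was seen and before any test was run. Levels in the text are group means with the SD between libraries. The test was limma on log2(CPM + 1) with a mean-variance trend, and log2 differences are given with their SE. Genes with at least 1 CPM in at least 3 libraries were tested (2 in the Isl1 fit), which left 17568 genes and 14595 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Adjusted p-values below come from limma unless another tool is named.

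The 18 libraries of the tissue and stage set were fitted together with 6 group means, and the contrasts were SAN against RA (mean of the 3 stages and at each stage), each pair of stages within a tissue, and the difference between tissues in the change from E14.5 to P14. Genes called with the same sign at all 3 stages were counted. The 7 Isl1 libraries were fitted apart from these, because the sets differed in depth and in which genes were listed. In that fit 4 CreNeg libraries were compared with 2 CrePos libraries, since the title of CrePos replicate 2 marks it as an outlier. The labels do not tie libraries to animals, so p-values measure the spread between these libraries. The labels number the replicates, but same-number SAN and RA libraries were not closer to each other than to others, as 3 of 9 pairs were best matched with their own number. A block by replicate number was run as an alternative only.

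The rule for named genes, the 30 gene lists and the first group of alternatives below were fixed before the data were examined. Named genes were Isl1, Hcn4, Tbx3, Shox2, Tbx18, Nppa, Gja1, Gja5 and Nkx2-5, the 6 largest changes in each direction (3 for stage, adjacent-step and interaction contrasts) among called genes whose groups did not overlap and whose higher mean was at least 5 CPM, and up to 4 members of each list with the smallest p. Gene models without a proper symbol, hemoglobins, histocompatibility genes, immunoglobulins, ribosomal proteins and mitochondrial genes were left out of the largest changes. A few genes under this rule are not reported here, while counts of calls and lists include them.

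The 30 lists covered pacemaker channels and junctions, SAN transcription factors and markers, working atrial myocardium, sarcomere, calcium handling, autonomic and cAMP signalling, potassium channels, sodium channels and conduction, BMP, Wnt and Notch signals, cell cycle, fatty acid oxidation, glycolysis, respiratory chain, p53 targets, immediate early and heat shock genes and sex-specific genes. The others were markers of autonomic neurons, glia and Schwann cells, fibroblasts, endothelium, smooth muscle and pericytes, epicardium and mesothelium, macrophages and leukocytes, ventricular myocytes, left atrium, erythroid cells, adipocytes, airway and lung, cartilage, and lymphocytes and thymus. The left atrial list held 2 genes, of which Bmp10 was also in the working atrial list, and is not used here. Lists with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01, adjusted over lists within a contrast, and again with an estimated correlation. Members called were also counted after their p-values were adjusted over the list alone. A list of 28 interferon-stimulated genes was written after 6 such genes had been seen among the largest changes.

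The first group of alternatives held a pseudocount of 0.5 or 4, no filter, a filter of 5, library weights, the replicate block, only the groups compared, equal upper quartiles, both sets in one fit of 24 libraries, all 7 Isl1 libraries with and without weights, and each library left out in turn. For gene lists they were the estimated correlation and limma's fry. Alternatives chosen after seeing the data were edgeR quasi-likelihood and DESeq2 on the recovered reads, the deposited scale, scaling on the sarcomere genes, and the sex of each library, which Y-linked genes put at 12 males and 13 females.

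The procedure was tested on simulated data with 200 changed genes. For the mean of 3 stages it recovered 58% of 2-fold and 93% of 4-fold changes. At E14.5 it recovered 10% and 62%, for the SAN from E14.5 to P14 15% and 71%, and for the Isl1 set 19% and 77%. Of the calls made, 3.21%, 5.26%, 5.49% and 9.43% in that order were false. The simulated genes varied independently and no shift was shared by a whole library, so these rates need not hold for the real libraries. The changed genes were also drawn only from those with a mean of at least 5 CPM. More genes were called in the data than in the simulations, so the adjusted threshold is more lenient there. Tools were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.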

Results

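Transcript levels were measured in laser-captured SAN, the pacemaker region of the heart, and in RA, the working atrial muscle beside it. There were 3 libraries per tissue at embryonic day 14.5 (E14.5), postnatal day 4 (P4) and postnatal day 14 (P14), which makes 18. These 18 came from mice with an Hcn4-GFP reporter. A further 7 libraries came from the SAN of E12.5 embryos with floxed Isl1 alleles and an Hcn4-GFP reporter, given tamoxifen at E10.5. Of these, 4 lacked a tamoxifen-inducible Cre recombinase (CreNeg) and 3 carried it (CrePos). Depth was 5101711 to 17997497 recovered reads in the 18 libraries and 45298052 to 88020475 in the 7. In the 7 libraries mt-Rnr2, a mitochondrial ribosomal RNA, took 21.4 to 34.1% of reads, while it was listed at 0 in the 18. A total of 6 genes were listed at 0 in all 18 and above 0 in all 7, so levels were not compared between the sets.

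The comparison of SAN with RA over the 3 stages asks which genes set the pacemaker region apart. Transcription factor genes of the node were far higher in SAN. Tbx3, a repressor of the working atrial programme, was higher by 5.80 ± 0.20 log2 units (SE, adjusted p = 4.0e-15, 9 libraries per tissue). Isl1, a LIM homeodomain factor, was higher by 5.43 ± 0.34 (adjusted p = 1.1e-10) and Shox2 by 5.15 ± 0.27 (adjusted p = 7.1e-12). Genes of the secreted atrial hormones and of fast conduction were far lower in SAN, with Bmp10 at −7.57 ± 0.29, Nppa at −7.43 ± 0.34 and Gja1 (connexin 43) at −3.18 ± 0.19. Mean Bmp10 was 1.73 CPM in SAN and 590 CPM in RA. Hcn4, the pacemaker channel gene, stood at 1687 CPM in SAN and 15.9 CPM in RA (6.72 ± 0.19). Because staining for its protein checked the dissection, that value is a check of the capture and not a finding.

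Among SAN transcription factors and markers, 8 of 10 tested genes were higher in SAN (9 adjusted over the list alone) and 0 lower (adjusted p = 5.9e-06 with an estimated correlation). Among them were Smoc2 at 5.31, Vsnl1 at 4.56 and Tbx18 at 1.69. Of 13 pacemaker channel and junction genes, 8 were higher (8 adjusted over the list alone) and 1 lower (adjusted p = 0.0020 with an estimated correlation). They included the calcium channel genes Cacna2d2 at 2.17 and Cacna1d at 2.11, while Kcnj3, a subunit of the acetylcholine-activated potassium channel, was lower at −1.66. Of 13 working atrial genes, 9 were lower (9 adjusted over the list alone) and 0 higher (adjusted p = 0.0067 with an estimated correlation), including Nppb at −5.19, Gja5 at −2.79 and Nkx2-5 at −1.86. Other large differences were Alox8 at 5.91, Odz4 (a teneurin) at 5.38, Sall1 at −4.70, the potassium channel gene Kcnh7 at −4.68 and Npr3, a natriuretic peptide receptor of endocardium, at −4.27.

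**Figure D1:**
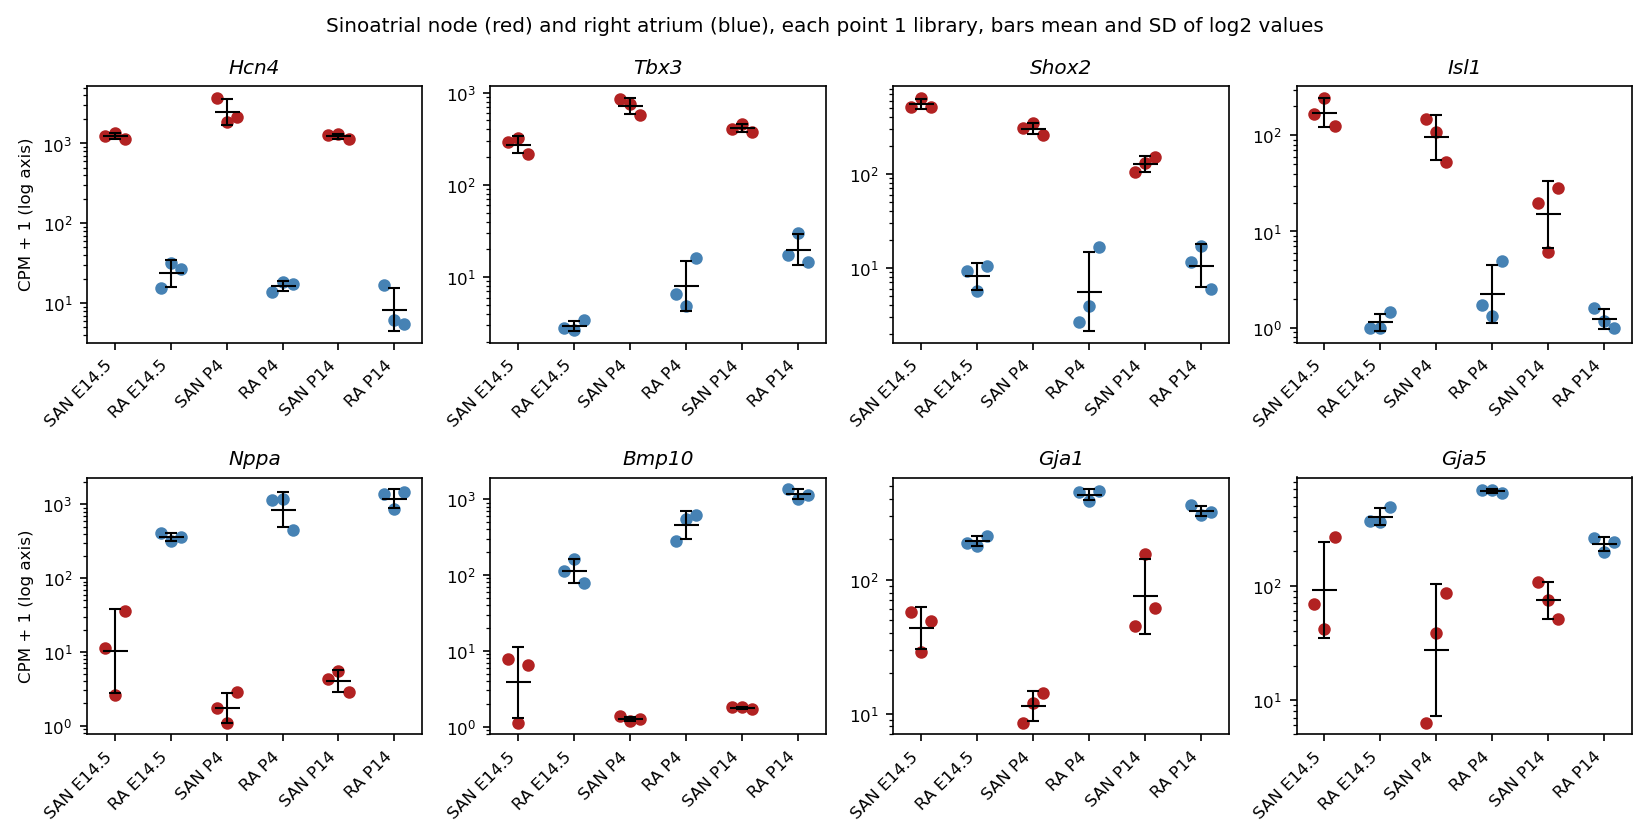
Levels of 8 genes in SAN (red) and RA (blue) at E14.5, P4 and P14, as CPM plus 1 on a log axis, where points are libraries and bars the mean and SD of the log2 values of 3 libraries. Tbx3, Shox2, Isl1 and Hcn4 lie higher in SAN and Nppa, Bmp10 and Gja1 lie higher in RA at each stage, while Gja5 means were 125 CPM in SAN and 403 CPM in RA at E14.5.

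Signalling lists held genes called in both directions. Of 22 autonomic and cAMP genes, 10 were higher in SAN and 2 lower (the same counts adjusted over the list alone; adjusted p = 0.19 with an estimated correlation). Rgs4, a regulator of G protein signalling, was at 5.01, Rgs6 at 2.02, Adcy1 at −3.34 and Rgs2 at −2.32. Of 22 BMP, Wnt and Notch genes, 7 were higher and 5 lower (11 and 6 adjusted over the list alone), with Bmp2 at 4.14, Bmp4 at 3.02 and Sfrp1 at 1.70 higher. Of 13 sodium channel and conduction genes, 7 were lower, including Scn10a at −3.05, and 2 higher (7 and 3 adjusted over the list alone; adjusted p = 0.053 with an estimated correlation). In calcium handling, Pln (phospholamban) was higher at 2.24 and Ryr3 lower at −3.14, with 2 of 20 genes higher and 4 lower (3 and 4 adjusted over the list alone). Among 21 potassium channel genes 1 was higher and 4 lower, the same adjusted over the list alone, and 3 were higher on sarcomere scaling. The 20 sarcomere genes split into 5 higher and 5 lower (6 and 6 adjusted over the list alone), with Myom2 at −2.36 and Tpm1 at 0.75.

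Metabolic lists were higher in SAN under camera at the preset correlation but did not pass with an estimated one. At the preset correlation adjusted p was 0.038 for fatty acid oxidation, 0.00074 for glycolysis and 0.0012 for the respiratory chain. Of 21 fatty acid oxidation genes 3 were higher, including Fabp3 at 1.25, and 1 lower (7 and 2 adjusted over the list alone; adjusted p = 0.43 with an estimated correlation), while on sarcomere scaling 8 were higher and 0 lower. Glycolysis had 5 of 19 higher, the same adjusted over the list alone, including Pgam1 at 0.82 (adjusted p = 0.20 with an estimated correlation), and 7 on sarcomere scaling. The respiratory chain had 3 of 21 (9 adjusted over the list alone; adjusted p = 0.31 with an estimated correlation), and 9 on sarcomere scaling. At P14 it had 0 of 21, with a median of −0.15 (camera adjusted p = 0.0050, and 0.35 with an estimated correlation), and the medians of fatty acid oxidation and glycolysis were −0.03 and −0.06. Of 23 cell cycle genes 2 were lower, Cenpf at −0.75 and Kif20a at −0.93, also adjusted over the list alone (adjusted p = 0.26 with an estimated correlation). Of 14 p53 targets 2 were higher, Ccng1 at 0.51 and Btg2 at 0.67, and of 16 immediate early and heat shock genes 1, Egr1 at 0.99, both unchanged in number adjusted over the list alone.

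Markers of other cell types were called in both directions. Endothelial markers were lower in SAN for 8 of 14 genes and higher for 1 (10 and 1 adjusted over the list alone; adjusted p = 0.064 with an estimated correlation), with Emcn at −2.20 and Eng at −1.53. Fibroblast markers were higher for 7 of 16 and lower for 1 (8 and 1 adjusted over the list alone; adjusted p = 0.34 with an estimated correlation), with Pdgfra at 1.27 and Fn1 at −1.29. Smooth muscle and pericyte markers were higher for 4 of 11 (7 adjusted over the list alone; adjusted p = 0.21 with an estimated correlation), with Myh11 at 3.06. Neuron markers were higher for 4 of 12 and lower for 2, also adjusted over the list alone, with Th, which makes catecholamine precursors, at 3.56 and Uchl1 at 3.55. Glial markers were higher for 3 of 9 and lower for 1 (5 and 1 adjusted over the list alone; adjusted p = 0.17 with an estimated correlation), with Sox10 at 2.06. Ventricular markers were higher for 1 of 5, Lbh at 1.21 (2 adjusted over the list alone; adjusted p = 0.19 with an estimated correlation). Cartilage markers were higher for 1 of 5, Sox9 at 0.81 (2 adjusted over the list alone; adjusted p = 0.16 with an estimated correlation). Epicardial markers were higher for 1 of 12, Msln, and lower for 1, Aldh1a2 at −1.22, and macrophage markers higher for 1 of 15, Mrc1 at 1.01. Adipocyte markers were higher for 2 of 4, Fabp4 and Cidea, and erythroid markers were lower for 1 of 11 (0 adjusted over the list alone). None of the 5 sex-specific and 3 lymphocyte genes passed, and no airway gene was tested.

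In total 2016 of 17568 genes were called by limma, 1074 higher and 942 lower in SAN. The split depended on scaling, with 974 higher and 1083 lower under equal upper quartiles (median of all genes −0.05, from −0.01). On sarcomere genes it was 1690 and 611 (median 0.13), and with library weights 1367 and 1384. The calls of Msln, Acsl1, Uqcrc2 and Rgs5 were each lost when any of at least 10 libraries was left out singly, with adjusted p up to 0.0833 without SAN E14.5 replicate 3 for Msln.

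Each stage was compared to ask which differences hold through development. At E14.5 the receptor gene Cckar was higher in SAN by 7.48 ± 0.56 (307 ± 37.4 against 0.940 CPM, SD, n = 3), with Isl1 at 7.26, Smoc2 at 7.03, Tbx3 at 6.54, Shox2 at 6.09 and Tbx18 at 1.52. Lower were Nppa at −5.16 ± 0.59, Bmp10 at −4.88, Adh6b at −4.24 and Gja1 at −2.16. At P4 Alox8 was higher at 6.74 ± 0.44, Tbx3 at 6.49, Shox2 at 5.77, Isl1 at 5.42 and Tbx18 at 1.41. Lower at P4 were Nppa at −8.92 ± 0.59, Bmp10 at −8.49, Thbs4 at −6.46, Gja1 at −5.25, Gja5 at −4.61 and Nkx2-5 at −2.30. The Nkx2-5 call was lost without RA P4 replicate 2 (adjusted p = 0.0676). At P14 Odz4 was higher at 6.35 ± 0.39, Tbx3 at 4.38, Isl1 at 3.61, Shox2 at 3.59 and Tbx18 at 2.14. Hmcn2 stood at 99.1 ± 39.6 CPM (SD, n = 3) in SAN and was listed at 0 in RA. Lower at P14 were Bmp10 at −9.35 ± 0.50, Nppa at −8.20, Nppb at −7.73 and Gja1 at −2.12. Hcn4 differed by 5.72, 7.23 and 7.22 at the 3 stages, again as a check of the capture.

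Some working atrial genes did not pass at each stage. Gja5 differed by −2.13 ± 0.63 at E14.5 (adjusted p = 0.0502) and −1.64 at P14 (adjusted p = 0.17). Nkx2-5 differed by −1.64 at E14.5 and −1.64 at P14 (adjusted p = 0.078 and 0.089). As a list, working atrial genes were lower for 5 of 13 and higher for 1, Sln, at E14.5 (8 and 2 adjusted over the list alone; adjusted p = 0.15 with an estimated correlation). They were lower for 10 of 13 at P4, the same adjusted over the list alone, and 7 of 13 at P14 (11 adjusted over the list alone), with adjusted p = 0.0065 and 0.0034 with an estimated correlation. Pacemaker genes were lower for 0, 1 and 1 and higher for 6, 5 and 7 of 13 at E14.5, P4 and P14 (8, 6 and 8 adjusted over the list alone; adjusted p = 0.00076, 0.0084 and 0.0097 with an estimated correlation). Markers of epicardium were lower in SAN for 3 of 12 at E14.5 (8 adjusted over the list alone; adjusted p = 0.15 with an estimated correlation). At P4 they were higher for 4 of 12 (4 adjusted over the list alone; adjusted p = 0.35 with an estimated correlation). Endothelial markers were lower for 9 of 14 at E14.5 (10 adjusted over the list alone; adjusted p = 0.058 with an estimated correlation). At P14, 5 of 11 smooth muscle, 4 of 9 glial, 4 of 16 fibroblast and 2 of 15 macrophage markers were higher in SAN, with 0 lower in each. Adjusted over the list alone these were 5, 4, 11 and 2. With an estimated correlation their adjusted p was 0.32, 0.075, 0.32 and 0.23. Endothelial markers were lower for 3 of 14 at P14. The ventricular gene Myl2 stood at 829 CPM in SAN E14.5 replicate 1 and at most 24.5 CPM in the other 17 libraries. That library is 1 of the 3 behind each SAN E14.5 mean and the comparisons built on it. Whether its capture held ventricular tissue was not tested.

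Limma called 936 genes at E14.5 (393 higher and 543 lower in SAN), 1047 at P4 (521 and 526) and 799 at P14 (564 and 235), and 174 at all 3 stages (113 and 61). Shared calls exceeded independence, with 173 higher in SAN at both E14.5 and P4 where 11.7 were expected, 129 at both E14.5 and P14 where 12.6 were expected, and 230 at both P4 and P14 where 16.7 were expected. Higher in RA were 158, 64 and 153 shared genes, where 16.3, 7.26 and 7.04 were expected. The 3 contrasts share one estimate of spread per gene, which makes joint calls more likely, so these expected numbers are too low. The P14 median of all genes was 0.10 and moved to −0.07 with equal upper quartiles (386 higher and 335 lower) and to 0.48 on sarcomere genes (2062 and 164), with 287 and 239 in edgeR and 558 and 421 in DESeq2. At P4 sarcomere scaling moved the median from −0.07 to 0.07 (707 and 392), and edgeR gave 347 and 309 at E14.5. The E14.5 count was 579 without SAN replicate 1, 583 without SAN replicate 2, 622 without RA replicate 1 and 583 without RA replicate 2, while the P14 count was 464 without RA replicate 2.

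The SAN comparison of P14 with E14.5 asks how the node matures. Among the largest rises were Cntn2, a contactin of conduction tissue, by 8.10 ± 0.69 (0.604 to 437 ± 72.5 CPM, SD, n = 3, adjusted p = 3.2e-08) and Lynx1 by 6.57 ± 0.34. Kcna1, a potassium channel, was listed at 0 at E14.5 and stood at 107 ± 31.4 CPM at P14. Hamp, which encodes the iron hormone hepcidin, rose by 7.53 ± 0.52 and Igfbp7 by 6.76 ± 0.42. Among the largest falls were Cited1 at −6.33 ± 0.43, Cckar at −6.25 ± 0.56, the slow skeletal troponin gene Tnni1 at −6.25 ± 0.22, Bmp7 at −5.93, Nrk at −5.77 and Hif3a at −5.60. Node transcription factors fell as well, with Isl1 at −3.52 ± 0.58 (adjusted p = 0.00012), Shox2 at −2.12 ± 0.47 and Tbx18 at −1.35 ± 0.24, while Tbx3 at 0.59 (adjusted p = 0.23) and Hcn4 at −0.01 did not pass.

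Of the 10 SAN transcription factors and markers, 5 fell and 0 rose (6 and 0 adjusted over the list alone; adjusted p = 0.088 with an estimated correlation), with Vsnl1 at −0.99. Of 13 pacemaker genes 5 rose and 1 fell (6 and 2 adjusted over the list alone), with Cacna1g at 3.29 and Cacna2d2 at −1.45. Potassium channel genes rose for 9 of 21 (9 with 1 falling adjusted over the list alone; adjusted p = 0.084 with an estimated correlation), with Kcnt2 at 4.89 and Kcnip2 at 3.28. Calcium handling had 5 of 20 rising and 2 falling (8 and 2 adjusted over the list alone; adjusted p = 0.23 with an estimated correlation), with Atp2a2, the sarcoplasmic calcium pump, at 1.11. Sodium channel genes had 3 of 13 rising and 1 falling (6 and 2 adjusted over the list alone), with Scn4b listed at 0 at E14.5. Autonomic genes had 4 of 22 rising and 2 falling, the same adjusted over the list alone, with the muscarinic receptor gene Chrm2 at 0.99. Sarcomere genes had 3 rising and 3 falling of 20 (4 and 4 adjusted over the list alone; 5 rose with equal upper quartiles and 6 on their own scale), with Tcap at 2.76 and Tnnc1 at −1.75. Their own scale holds the mean of this list equal in all libraries, so the count on it is no test of the list. All 23 cell cycle genes fell, also adjusted over the list alone (adjusted p = 0.043 with an estimated correlation), with Birc5 at −4.34 and Mki67 from 1012 ± 163 to 123 ± 23.3 CPM (SD, n = 3).

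In the metabolic lists of the node, glycolysis fell for 12 of 19 genes and rose for 2 (13 and 2 adjusted over the list alone; adjusted p = 0.17 with an estimated correlation), with the glucose transporter gene Slc2a1 at −3.26, Pgam1 at −1.43 and Gapdh at −1.32. Fatty acid oxidation rose for 7 of 21 and fell for 1, also adjusted over the list alone (adjusted p = 0.17 with an estimated correlation), with Acsl1 at 2.84 and Cd36 at 2.11. The respiratory chain rose for 2 of 21, also adjusted over the list alone (adjusted p = 0.45 with an estimated correlation), and for 4 under either other scaling. Immediate early and heat shock genes rose for 9 of 16 and fell for 1, also adjusted over the list alone (adjusted p = 0.084 with an estimated correlation), with Nr4a1 at 4.19 and Dusp1 at 3.69, genes known to respond rapidly to stimulation. Of 14 p53 targets 2 rose, including Btg2 at 3.30, and 1 fell, and of 22 BMP, Wnt and Notch genes 5 rose and 5 fell (6 and 9 adjusted over the list alone).

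Markers of other cell types moved with stage in the node. Macrophage markers rose for 12 of 15 genes (14 adjusted over the list alone; adjusted p = 0.043 with an estimated correlation), with Lyz2 from 7.12 to 231 ± 86.0 CPM (SD, n = 3). Fibroblast markers rose for 11 of 16 (13 adjusted over the list alone; adjusted p = 0.088 with an estimated correlation), with Mfap5 at 5.37 and Dcn at 4.00. Glial markers rose for 5 of 9 (7 adjusted over the list alone; adjusted p = 0.063 with an estimated correlation), with Cdh19 at 4.23. Endothelial markers rose for 6 of 14, also adjusted over the list alone (adjusted p = 0.23 with an estimated correlation). Smooth muscle markers rose for 6 of 11 and fell for 2, also adjusted over the list alone (adjusted p = 0.29 with an estimated correlation), with Myh11 at 6.92 and Rgs5 at 5.05. Epicardial markers rose for 4 of 12 (6 adjusted over the list alone; adjusted p = 0.30 with an estimated correlation). The calls of Upk1b, Msln and Lrrn4 among them were lost without SAN E14.5 replicate 1 (adjusted p = 0.164, 0.237 and 0.264). All 4 adipocyte markers rose, with Dio2 at 5.75. Neuron markers fell for 5 of 12 and rose for 2 (6 and 2 adjusted over the list alone), with Uchl1 at −3.36, Th at −3.22 and Dbh at 3.32. Erythroid markers fell for 6 of 11 (7 adjusted over the list alone; adjusted p = 0.42 with an estimated correlation).

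Limma called 4263 genes between P14 and E14.5 in SAN (1712 rose and 2551 fell). The median of all genes was −0.18 and moved to −0.05 with equal upper quartiles and −0.01 on sarcomere genes (2109 rose and 1836 fell), with 1971 and 1691 in edgeR and 2460 and 2036 in DESeq2.

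The steps between adjacent stages in SAN separate early from late change. From E14.5 to P4 Hamp rose by 5.42 ± 0.52, Lynx1 by 5.19 ± 0.34 and Nfasc, a neurofascin of axons, by 4.97, with Tbx3 at 1.40. Over that step Lin7a fell at −4.88, Dgkk at −4.45, Nppa at −2.54 and Gja1 at −1.94, and Arhgap36 reached 0. From P4 to P14 Hmcn2 rose by 6.14, Pi16 by 5.13, the complement gene C4b by 5.12 and Gja1 by 2.74. Over that step Tnni1 fell at −4.77 ± 0.22, Th at −4.24, Calca, a neuropeptide gene, at −3.80, Isl1 at −2.66 and Tbx18 at −0.97. The first-step calls of Nppa and Tbx3 were each lost in 3 of 20 alternatives (adjusted p up to 0.0993 and 0.0667). In the second step Isl1 was lost in 3 (up to 0.186) and Tbx18 in 7 (up to 0.107). Gja1 stood at 44.2, 10.6 and 86.3 CPM at E14.5, P4 and P14. Limma called 1448 genes in the first step (676 rose and 772 fell) and 982 in the second (471 and 511). The first count was 791 without SAN E14.5 replicate 1, 831 without SAN E14.5 replicate 2 and 842 without SAN P4 replicate 2, and the second 554 without SAN P4 replicate 2 and 547 without SAN P14 replicate 1. In edgeR the first split was 812 and 416 and in DESeq2 1229 and 748, while the second was 550 and 394 with equal upper quartiles and 805 and 214 on sarcomere genes, where its median moved from −0.08 to 0.17.

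The RA comparison of P14 with E14.5 asks the same of working atrial muscle. Among the largest rises were Dpt, a matrix protein gene, at 7.64 ± 0.52 (0.645 to 355 CPM, n = 3, adjusted p = 1.1e-09), and Podn at 7.35 ± 0.41. The myoglobin gene Mb rose by 7.34 ± 0.69 (8.98 to 1608 ± 198 CPM, SD, n = 3) and Fndc5 by 6.65 ± 0.38, and Hamp went from listed at 0 to 171 CPM. The largest falls included Bmp7 at −6.61 ± 0.41, Dlk1 at −6.15, Hif3a at −5.93, Igfbp2 at −5.88, Dgkk at −5.70, Acvr1c at −5.66 and Tnni1 at −4.52 ± 0.22. Working atrial genes rose for 6 of 13, also adjusted over the list alone (adjusted p = 0.093 with an estimated correlation). Among them were Bmp10 at 3.37, Nppb at 2.96, Sln at 2.71 and Nppa at 1.72 (adjusted p = 0.040), a call lost in 9 of the alternatives, with adjusted p = 0.113 without RA E14.5 replicate 2. Of node genes Tbx3 rose by 2.75 ± 0.34 from 1.96 to 19.8 CPM, while Tbx18 fell at −1.97 and Vsnl1 at −1.65. Hcn4 fell at −1.51 ± 0.34, from 23.6 to 8.51 CPM (adjusted p = 0.0022), and with edgeR its adjusted p was 0.065, the highest of its alternatives.

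In RA the respiratory chain rose for 16 of 21 genes, also adjusted over the list alone, with Cox8b at 2.35, Cycs at 1.39 and Slc25a4 at 1.10 (adjusted p = 0.031 with an estimated correlation). Fatty acid oxidation rose for 11 of 21 (13 adjusted over the list alone; adjusted p = 0.031 with an estimated correlation), with Acsl1 at 3.24. On sarcomere scaling these were 9 and 6 rising, and with equal upper quartiles 17 and 16. Potassium channels rose for 7 of 21 (8 adjusted over the list alone; adjusted p = 0.023 with an estimated correlation), with Kcnip2 at 5.34, Kcnj3 at 2.67 and Kcnj5 at 1.98. Autonomic and cAMP genes rose for 9 of 22 (9 with 3 falling adjusted over the list alone; adjusted p = 0.041 with an estimated correlation), with Rgs4 at 3.02, Chrm2 at 2.29 and Gnao1 at 1.27. Immediate early genes rose for 6 of 16 (8 adjusted over the list alone; adjusted p = 0.031 with an estimated correlation), with Egr1 at 4.49. All 23 cell cycle genes fell, also adjusted over the list alone (adjusted p = 0.031 with an estimated correlation), with Mki67 from 1148 ± 105 to 148 ± 19.0 CPM (SD, n = 3).

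Sarcomere genes rose for 10 of 20 and fell for 2 (10 and 5 adjusted over the list alone; adjusted p = 0.12 with an estimated correlation), with Tcap at 3.28, and on sarcomere scaling 6 rose and 6 fell. Sarcomere scaling holds the mean of this list equal in all libraries, so that split is no test of its rise. Calcium handling rose for 5 of 20 and fell for 4, also adjusted over the list alone (adjusted p = 0.21 with an estimated correlation), with Atp2a2 at 1.66 and Ryr2 at 1.51. Pacemaker genes rose for 5 of 13 and fell for 2, also adjusted over the list alone (adjusted p = 0.069 with an estimated correlation). SAN transcription factors and markers split 3 and 3 of 10, with Smoc2 rising by 1.89. Sodium channel genes rose for 3 of 13 and fell for 2 (adjusted p = 0.18 with an estimated correlation). Glycolysis rose for 4 of 19 and fell for 6, including Slc2a1 at −3.30, with 6 and 4 under equal upper quartiles and 3 and 10 on sarcomere genes. BMP, Wnt and Notch genes rose for 3 of 22 and fell for 5 (5 and 6 adjusted over the list alone), with Heyl at 3.48, and p53 targets rose for 3 of 14, with Perp at 2.85, and fell for 1.

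Markers of other cells moved in RA too. Fibroblast markers rose for 12 of 16 and fell for 1, also adjusted over the list alone (adjusted p = 0.060 with an estimated correlation). Smooth muscle markers rose for 5 of 11, with Rgs5 at 5.94, and fell for 1, Cnn1 at −5.02 (5 and 2 adjusted over the list alone; adjusted p = 0.27 with an estimated correlation). Macrophage markers rose for 2 of 15 and glial markers for 2 of 9 (the same adjusted over the list alone; adjusted p = 0.12 and 0.14 with an estimated correlation), and with equal upper quartiles 4 macrophage markers rose. Adipocyte markers rose for 3 of 4, with Fabp4 at 5.12, and neuron markers rose for 1 of 12, Dbh at 4.13, and fell for 3. Epicardial markers fell for 4 of 12, including Bnc1 at −3.75, and the calls of Upk1b and Lrrn4 were lost without RA P14 replicate 2 (8 adjusted over the list alone; adjusted p = 0.46 with an estimated correlation). Erythroid markers fell for 9 of 11 (11 adjusted over the list alone; adjusted p = 0.15 with an estimated correlation), with the embryonic globin genes Hbb-y at −8.34 and Hba-x at −7.81. Of 14 endothelial markers 2 rose and 1 fell (1 and 3 on sarcomere genes), and 3 of 5 cartilage markers fell.

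**Figure D2:**
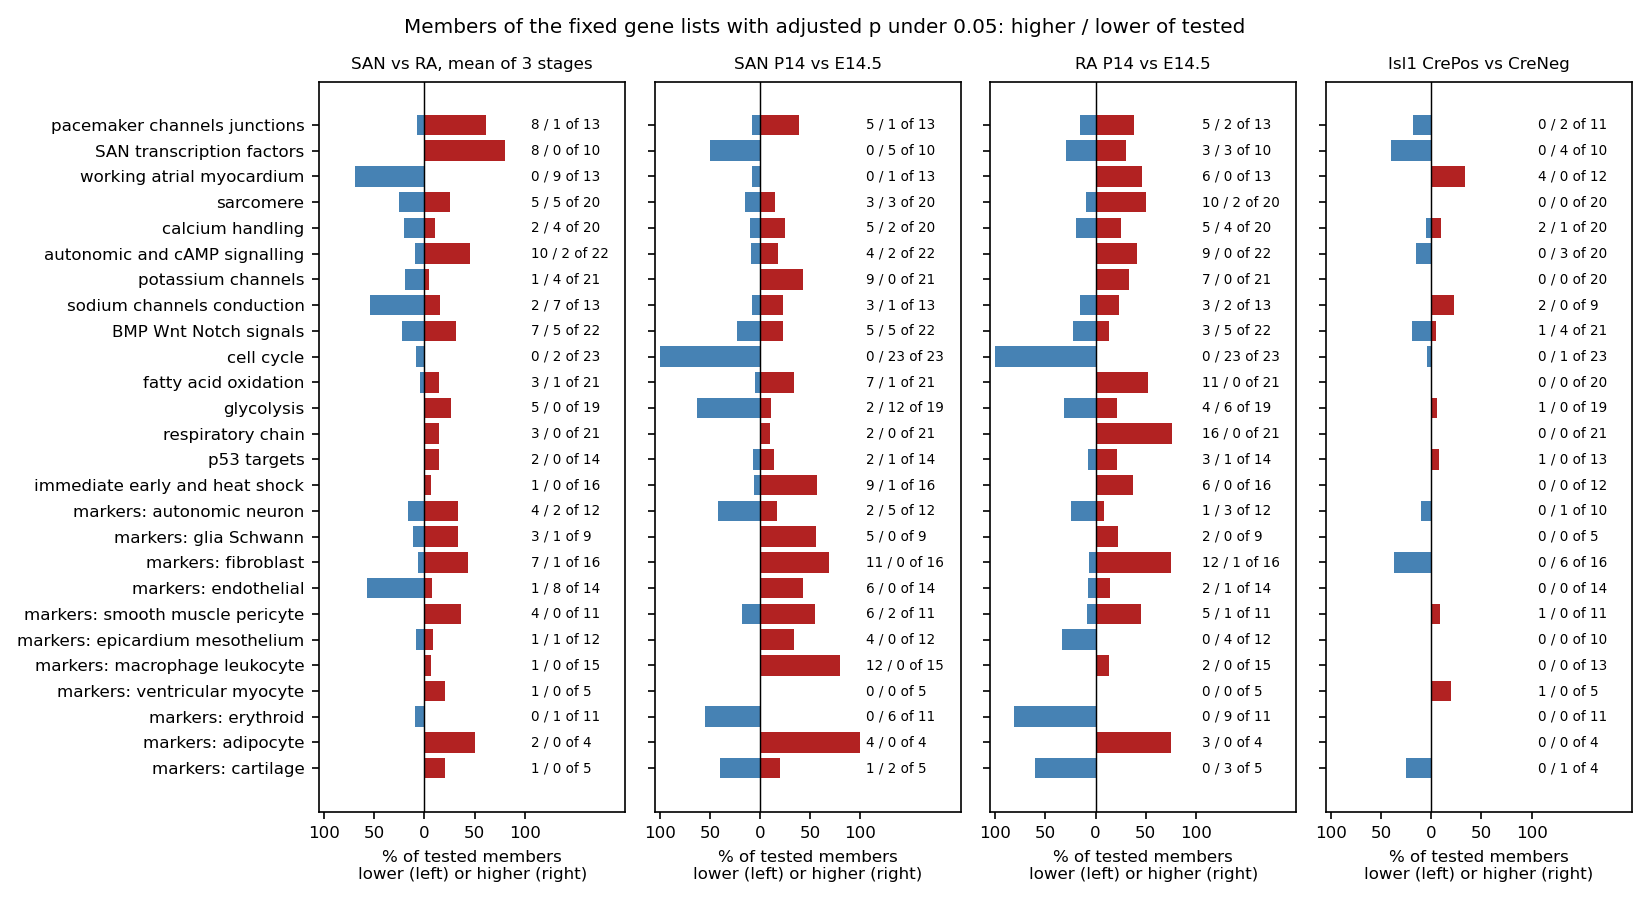
Percent of the tested members of each gene list called higher (right) or lower (left) in SAN against RA over the 3 stages, in P14 against E14.5 for SAN and RA, and in the Isl1 set. All 23 cell cycle genes fell in both tissues from E14.5 to P14, and 16 of 21 respiratory chain genes rose in RA and 2 in SAN, where on sarcomere scaling they were 9 and 4 and the difference between tissues was not tested.

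Limma called 3988 genes between P14 and E14.5 in RA (1052 rose and 2936 fell). Both tissues together had 642 shared rising genes where 103 were expected under independence and 1499 shared falling genes where 426 were expected, with 43 in opposite directions. Both contrasts share one estimate of spread per gene, so the expected numbers are too low here as well. The median of all genes was −0.37, −0.06 with equal upper quartiles (1597 rose and 1547 fell) and −0.66 on sarcomere genes (755 and 5250). The split was 1567 and 1151 in edgeR and 1904 and 1554 in DESeq2, so falls in RA are to be read relative to these shifts.

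In RA from E14.5 to P4 Dpt rose by 7.64 ± 0.52, Nov, a matricellular protein gene, by 6.74, Mb by 5.79 ± 0.69, Tbx3 by 1.44 and Gja1 by 1.16. Igfbp2 fell at −5.95 and the mesothelial genes Upk3b at −5.39 and Lrrn4 at −5.10. From P4 to P14 Hamp rose by 6.94 ± 0.52, Ptprt by 4.80, Cilp2 by 4.50 and Tbx3 by 1.31, while Clca1 fell at −4.46, Tnni1 at −3.60, Ntrk3 at −3.42 and Tbx18 at −1.71. The Gja1 call was lost whichever of the 6 libraries was left out (adjusted p up to 0.110) and in 11 of 20 alternatives (up to 0.115). The Tbx3 calls were each lost in 4 alternatives, with adjusted p up to 0.135 in the first step and 0.166 in the second. Limma called 1193 genes in the first step (568 rose and 625 fell) and 1188 in the second (236 and 952). The first median was −0.11 and −0.41 on sarcomere genes (365 and 1541), with 587 and 303 in edgeR and 854 and 566 in DESeq2. The second median was −0.24 and 0.06 with equal upper quartiles (440 and 286), with 328 and 230 in edgeR and 615 and 494 in DESeq2. The first count was 760 without RA E14.5 replicate 1, 766 without RA E14.5 replicate 3 and 788 without RA P4 replicate 3. The second was 704 and 676 without RA P4 replicates 2 and 3 and 742, 632 and 764 without RA P14 replicates 1, 2 and 3.

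The interaction asks which genes changed differently in SAN and RA from E14.5 to P14. Cntn2 rose more in SAN, by 4.58 ± 0.98 on the log2 scale (0.604 to 437 CPM in SAN and 0.738 to 34.9 CPM in RA, n = 3). Hmcn2 differed by 7.26 ± 0.67, with a change of 5.80 in SAN and −1.46 in RA. Fam163a differed by 6.41, with 3.99 in SAN and −2.42 in RA. Fndc5 rose more in RA (−5.25 ± 0.54), from 4.44 to 536 CPM there and from 22.5 to 62.8 CPM in SAN. Negative differences (SAN minus RA) included Isl1 at −3.64 (adjusted p = 0.021, a call lost in 10 alternatives), Tbx3 at −2.16, Shox2 at −2.49 (adjusted p = 0.048, lost in 18) and Cckar at −5.88. Isl1, Shox2 and Cckar changed by −3.52, −2.12 and −6.25 in SAN and by 0.12, 0.37 and −0.38 in RA. A gene with hardly any reads in RA cannot fall much there on log2(CPM + 1). Such differences therefore show a fall in SAN and cannot tell how RA would have changed. The highest adjusted p over the alternatives was 0.351 for Isl1, 0.136 for Shox2 and 0.0736 for Tbx3. Tbx18 at 0.62 (adjusted p = 0.42) did not pass. Working atrial Nppb was at −5.14 and Bmp10 at −4.48, while Nppa at −3.04 (adjusted p = 0.057) and Hcn4 (adjusted p = 0.10) did not pass.

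Limma called 399 genes for this difference (288 positive and 111 negative). The median of all genes was 0.18, −0.00 with equal upper quartiles (209 and 184) and 0.64 on sarcomere genes (1458 and 80), with 117 and 112 in edgeR and 387 and 288 in DESeq2. The count was 190 without SAN E14.5 replicate 1, 221 without SAN E14.5 replicate 2, 206 and 191 without RA E14.5 replicates 1 and 2, and 262, 224 and 262 without RA P14 replicates 1, 2 and 3.

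The Isl1 set asks how embryonic SAN tissue differs when Isl1 deletion is induced. Isl1 reads stood at 67.4, 88.5, 47.8 and 83.2 CPM in the 4 CreNeg libraries, and at 71.7, 2.85 and 53.9 CPM in the CrePos libraries of replicates 1, 2 and 3. Replicate 2 is the library titled as an outlier and was left out, so Isl1 differed by −0.16 ± 0.28 (adjusted p = 0.73) between the 2 remaining libraries labelled CrePos and the 4 CreNeg. Whole-gene reads include parts outside any deleted exon, so this total cannot check the deletion.

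In the libraries labelled CrePos, Bmp4, a BMP ligand gene, was lower, at 5.51 ± 0.0430 against 99.7 ± 25.3 CPM (SD, n = 2 and 4; −3.91 ± 0.29, adjusted p = 2.8e-06). Cckar was lower by a log2 difference of −6.29 ± 0.33, Rgs4 at −5.15 ± 0.38 and Csmd1 at −3.97 ± 0.41. Node genes were lower as well, with Tbx3 at −2.80 ± 0.44 and Hcn4 at −1.25 ± 0.22, while Gja5 of working atrial muscle was higher at 3.19 ± 0.50. Interferon-stimulated genes were the largest rises, with Ifit1 at 6.05 ± 0.59 (108 ± 54.8 against 0.899 CPM), Ifi44 at 5.72, Usp18 at 5.37, Isg15 at 4.78, Rsad2 at 4.77 and Mx2 at 4.42.

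Of 10 SAN transcription factors and markers, 4 were lower (7 adjusted over the list alone; adjusted p = 0.17 with an estimated correlation), among them Smoc2 at −1.85 and Vsnl1 at −1.14. Shox2 at −0.82 (adjusted p = 0.10) and Tbx18 at −0.61 did not pass. Of 12 working atrial genes 4 were higher (6 adjusted over the list alone; adjusted p = 0.028 with an estimated correlation), with Smpx at 1.46 and Nppa at 2.51. Pacemaker genes were lower for 2 of 11 (3 adjusted over the list alone; adjusted p = 0.28 with an estimated correlation), and Cacna1g at −2.15 had adjusted p = 0.055. Autonomic genes were lower for 3 of 20 (4 adjusted over the list alone; adjusted p = 0.46 with an estimated correlation), with Chrm2 at −2.14 and Adora1 at −1.65. BMP, Wnt and Notch genes were lower for 4 of 21 and higher for 1 (7 and 3 adjusted over the list alone), with Sfrp2 at −1.83, Wnt5a at −1.57 and Dkk3 at 1.77. Calcium handling had Ryr3 at 2.25 and Casq1 at 1.63 higher and Pln at −1.86 lower (2 and 2 adjusted over the list alone; adjusted p = 0.24 with an estimated correlation). Sodium channels had 2 of 9 higher (3 with 1 lower adjusted over the list alone; adjusted p = 0.13 with an estimated correlation). Of 13 p53 targets Cdkn1a, a cell cycle inhibitor gene, was higher at 2.88 (5 adjusted over the list alone; adjusted p = 0.17 with an estimated correlation).

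Fibroblast markers were lower for 6 of 16 genes (11 adjusted over the list alone; adjusted p = 0.26 with an estimated correlation), with Pdgfra at −1.91 and Mfap4 at −1.55. That count depended on scaling, with 2 under equal upper quartiles and 8 on sarcomere genes. Other markers called were Uchl1 at −1.48 of neurons, Myh11 at 2.09 of smooth muscle, Sox9 at −2.62 of cartilage and Myl3 at 1.42 of ventricle, and of metabolic and cell cycle genes Slc2a1 at 1.13 higher and Mki67 lower. Of 21 alternatives the Mki67 call was lost in 16 (adjusted p up to 0.727), Slc2a1 in 10 (0.479) and Mfap4 and Myl3 in 9. On sarcomere genes no cell cycle or glycolysis gene was called, and with equal upper quartiles no cell cycle gene. No member of the sarcomere, potassium channel, fatty acid oxidation, respiratory chain, immediate early, glial, endothelial, epicardial, macrophage or erythroid list was called, while with equal upper quartiles 1 fatty acid oxidation and 1 respiratory chain gene were higher. Relative to other genes the sarcomere, fatty acid oxidation, respiratory chain and immediate early lists were higher under camera (adjusted p = 0.26, 0.17, 0.28 and 0.26 with an estimated correlation).

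**Figure D3:**
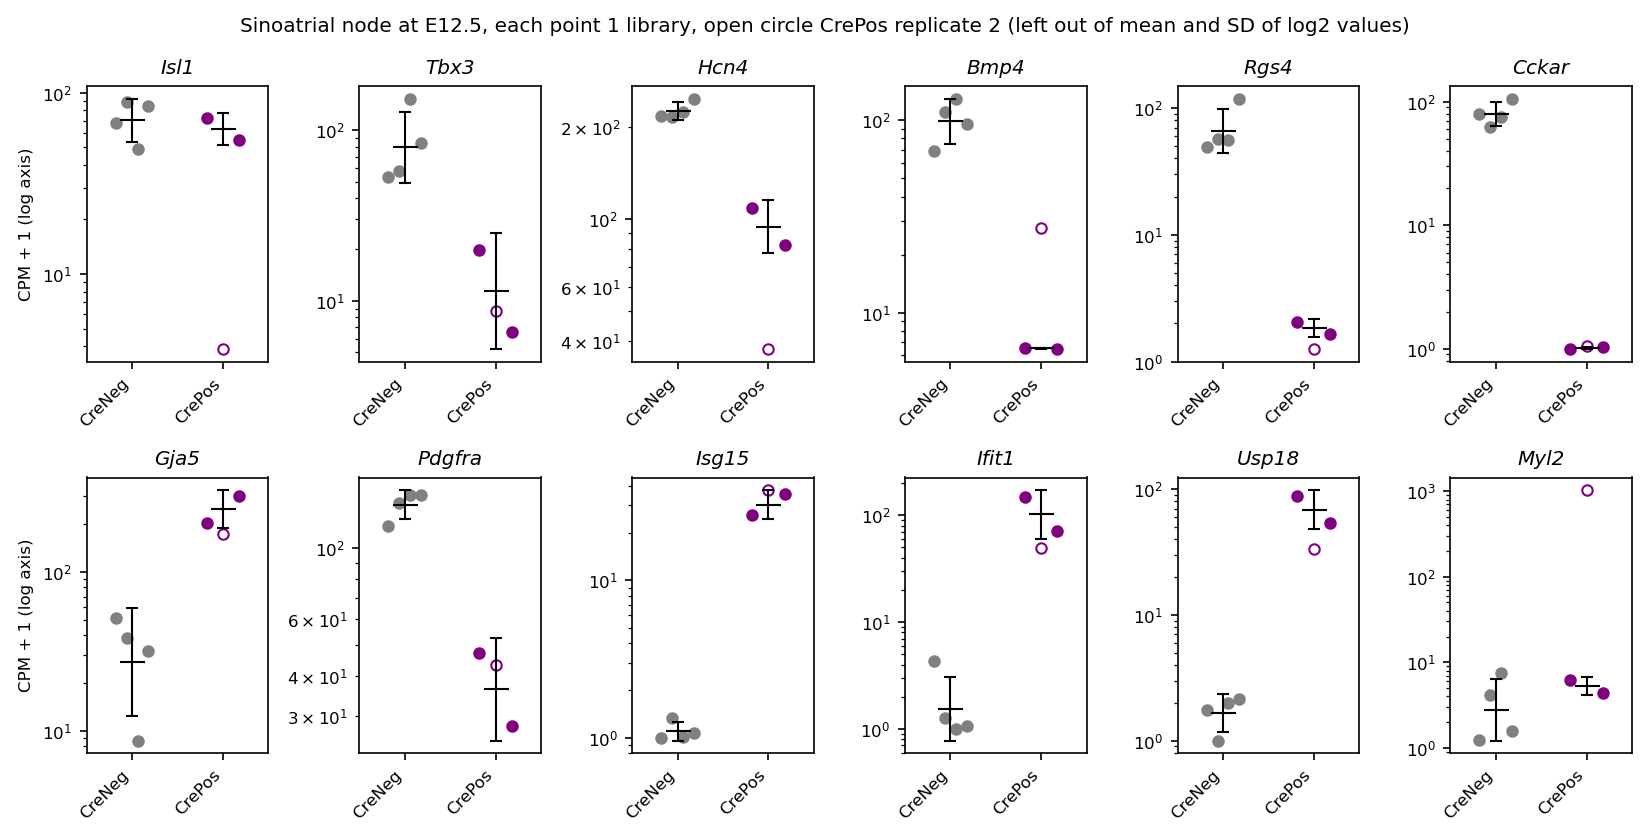
Levels of 12 genes in the 4 CreNeg and 3 CrePos libraries, as CPM plus 1 on a log axis, where points are libraries, the open circle is CrePos replicate 2 and bars are the mean and SD of the log2 values without it. Isl1 lies at 71.7 and 53.9 CPM in the filled CrePos points and at 2.85 CPM in the open one.

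Limma called 292 of 14595 genes (99 higher and 193 lower), from a median of all genes of −0.42. With equal upper quartiles the median was 0.02 (175 higher and 69 lower), on sarcomere genes −0.56, and the split was 61 and 15 in edgeR and 382 and 374 in DESeq2. Of the 292 limma calls only 65 were also called in edgeR with the same sign, and 25 of 40 named calls were lost in edgeR. Without CrePos replicate 3 the count was 42, and the calls of Tbx3, Hcn4 and Gja5 were lost (adjusted p = 0.192, 0.171 and 0.202) with each other named call except Ifit1, Usp18, Rsad2, Mx2, Cckar, Rgs4, Csmd1, Bmp4 and Pdgfra. Isg15 and Ifi44 were not tested where a CrePos library was left out. Rsad2 was lost without CrePos replicate 1 (0.0574), and of 40 named calls 6 were tested and kept in each alternative, namely Usp18, Cckar, Rgs4, Csmd1, Bmp4 and Pdgfra.

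The genes higher in SAN than RA at E14.5 were followed into the Isl1 set, to ask whether they moved as a group. Of 372 such genes 83.3% were lower in the libraries labelled CrePos, with a median of −0.80 against −0.42 for all genes (camera p = 8.0e-11, and p = 0.18 with an estimated correlation). Of these 68 fell where 4.94 were expected by chance, while 1 rose. The number that fell was 41 with equal upper quartiles, 17 with no filter and 15 without CrePos replicate 3. Of 463 genes higher in RA, 27 rose where 3.08 were expected and 2 fell, with a median of 0.02 (camera p = 2.2e-18, and p = 0.078 with an estimated correlation). With equal upper quartiles the SAN median was −0.37, and it ran from −1.05 without CrePos replicate 1 to −0.51 without CrePos replicate 3.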

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

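The tests of leukocytes, sex, dilution, scaling, ventricular tissue and a library mix-up, and the look at interferon genes in CrePos replicate 2, were chosen only after the result was seen, and the interferon list was written after 6 of its kind had been named.

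Interferon-stimulated genes rose in the 2 libraries labelled CrePos, as a signal that no comparison was built for. Apart from the 6 named, 25 of 28 listed genes were tested, with a median of 2.77 where 10000 random lists gave −0.65 to −0.17, and 17 were called, which argues against a chance pick of the largest genes. More leukocytes would have raised their markers, whose median was −0.72 against −0.42 for all genes. That list did not differ from other genes (camera p = 0.88 at the preset correlation). Its members moved together (estimated correlation 0.77), so with 2 CrePos libraries a small rise of leukocytes cannot be excluded. Of the 25 interferon genes, 22 were higher than in both CreNeg libraries of the same sex in each sex. CrePos replicate 2, outside that fit, was above each CreNeg library for 28 of the 31 genes, the 6 named included. Its levels were 48.8 for Ifit1, 49.9 for Ifi44, 32.1 for Usp18, 36.4 for Isg15, 22.9 for Rsad2 and 15.8 CPM for Mx2. An interferon response tied to Cre or to the loss of Isl1 may explain the rise, but Cre and genotype go together in this design, and shared paralog reads and animals stay open.

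Genes enriched in SAN were lower in the libraries labelled CrePos. One dilution of the node by tissue lacking these genes would lower the strongly enriched ones by about 1 common amount. The 58 genes taken were called at least 8-fold higher in SAN at E14.5 and had a CreNeg mean of at least 5 CPM. That level belongs to the comparison tested, which can enlarge the falls. Of these, 43.1% lay over 2 SE from their weighted mean of −1.68. The genes were picked against RA only, so another tissue may hold some of them, and the pseudocount shrinks the falls of low genes. The spread therefore cannot decide whether the node was diluted. Equal upper quartiles took the median of all genes to 0.02, and 41 of 383 such genes were still called lower where 1.83 were expected, which argues against scale as the whole cause. The list test with an estimated correlation gave p = 0.18 on the original scale. A fall of node genes after Isl1 loss may be part of this pattern, and dilution by other tissue or a mixture of several tissues stays open.

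CrePos replicate 2 held ventricular transcripts. Myl2 stood at 1032 CPM against at most 6.40 in the other 6 libraries, Myl3 at 776 against 121, Hey2 at 27.6 against 9.13 and Mpped2 at 14.7 against 14.0 CPM. That makes 4 of 5 ventricular markers highest there (not Lbh, at 79.9 against 88.4 CPM), which is consistent with ventricular myocardium in the capture, although Mpped2 is a near tie. A CreNeg library under this label would lack the interferon signal, yet 28 of the 31 genes were above each CreNeg library. Its other levels were 51.8 for Nppa, 171 for Gja5 and 2.60 CPM for Bmp10. A wrong label from outside the set stays open.

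In the 4 CreNeg libraries, 13 of 122 named genes had one library far from the other 3, where chance gives about 1 in 20 for normally distributed values. Levels in CPM need not follow that, and the genes are neither independent nor picked at random, so the number is not a test. The gap over the range was 0.924 for Ifit1, 0.930 for Mx2, 0.886 for Rgs4, 0.883 for Nppa, 0.939 for Pdk4, 0.868 for Eda2r, 0.897 for Fabp7, 0.996 for Aldh1a2, 0.842 for Bnc1, 0.951 for Gpm6a, 0.856 for Hey2, 0.925 for Epb4.2 and 0.945 for Col2a1.

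The change from E14.5 to P14 differed between SAN and RA, by the interaction term, for the named genes that follow. A gene with hardly any reads in one tissue cannot fall much there, so a difference may come from the other tissue alone. Positive differences (log2, SAN minus RA) were Cntn2 4.58, Scn4b 2.74, Flt1 1.52, Gpm6a 2.81, Upk1b 5.01, Lrrn4 6.58, Lyz2 2.95, Igfbp2 5.75, Acvr1c 3.87, Itpr2 1.32, Hmcn2 7.26 and Fam163a 6.41. Negative differences were Cckar −5.88, Tnni1 −1.73, Isl1 −3.64, Tbx3 −2.16, Shox2 −2.49, Nppb −5.14, Bmp10 −4.48, Tnnc1 −1.99, Adcy1 −3.31, Fabp4 −3.38, Dpt −4.77, Fndc5 −5.25, Kcnj5 −1.34, Smoc2 −3.85, Sln −2.69, Myh7 −1.60, Ryr2 −1.56, Gnao1 −0.97, Rgs4 −3.90 and Perp −2.55. Of the 9 that were followed through the alternatives 4 kept the call in each. It was lost in 3 for Lrrn4 (adjusted p up to 0.309), 2 for Cckar, 5 for Tbx3, 10 for Isl1 and 18 for Shox2.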

How the results depend on the processing

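Tests with edgeR, DESeq2, the deposited scale, sarcomere scaling and sex were chosen only after the data were seen. Of 292 alternative values for 14 counts, 238 stayed within 1.5 times. The median of the SAN-enriched genes kept its sign and its side of the camera threshold at the preset correlation in all 24 of its alternatives. With an estimated correlation, which was not among these 24, camera gave p = 0.18 in the main fit. Of 13808 values for 619 named-gene results 13053 kept their side of the threshold, 511 lost and 244 gained a call, with 0 reversed. The causes of the changes below were not tested. Weights gave 2914 genes at E14.5, 7640, 3117 and 3191 in RA (P14 and P4 against E14.5, then P14 against P4), 1397 for the interaction and 285 at all 3 stages. Only the groups compared gave 1546 at E14.5, 550 at P4, 311 in SAN and 778 in RA (P14 against P4) and 759 for the interaction. Equal upper quartiles gave 726 in RA (P14 against P4), and the deposited scale 234 for the interaction. Sarcomere scaling gave 2226 at P14, 6005 and 1906 in RA (P14 and P4 against E14.5) and 1538 for the interaction. edgeR gave 526 at P14, 558 in RA (P14 against P4) and 229 for the interaction, where DESeq2 gave 675. The limma calls that edgeR shared were 59.1%, 34.8% and 47.4% of these in that order, and 22.3% for Isl1. The Isl1 count was 39 with no filter, 459 in the fit of 24 libraries, 980 with the block, 123 on the deposited scale, 76 in edgeR and 756 in DESeq2, with 261 for all 7 libraries. The estimated correlation left 21 of 105 list calls.

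Leaving out one library in turn gave 1673 to 2217 genes for SAN against RA over the 3 stages, 579 to 894 at E14.5, 745 to 1371 at P4, 464 to 644 at P14 and 135 to 186 at all 3 stages. It gave 3168 to 3722, 791 to 1681 and 547 to 1147 in SAN, 2887 to 3348, 760 to 1104 and 632 to 900 in RA (P14 and P4 against E14.5, then P14 against P4), 190 to 451 for the interaction and 42 to 364 for Isl1. Where 1 CrePos library remains it is assumed to vary like the others. Genes that a filter or tool dropped gave no value there, as Isg15 and Ifi44 without CrePos replicate 1 or 3. Depth limits genes near 1 read, 0.00823 to 0.215 CPM.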

Other observations

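The tests by splits of libraries were written before any split was run, and that of all 7 Isl1 libraries was added only after the data were seen. For the comparisons of 3 libraries with 3 there are 10 splits, so a share under 0.05 cannot be reached; in each the real split, 1 of 10, gave the most genes. The highest of the others was 2 genes at E14.5, 8 at P4 and 4 at P14 for SAN against RA, 1, 2 and 9 in SAN (P14 and P4 against E14.5, then P14 against P4) and 0 in each RA comparison. Among 100 splits, the real split included and the rest drawn, only the real split gave as many as 2016 genes over the 3 stages (highest other 949). Only the real split gave as many as 174 at all 3 stages (highest other 0). For the interaction 2 gave as many as 399, the real split and another with 633. The drawn splits exchange SAN and RA libraries within a stage, so real tissue differences can enter this contrast. They therefore cannot tell whether 399 exceeds chance. Among 35 splits of all 7 Isl1 libraries only the real split gave as many as 261, with 8 in the highest other.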
